A study of Mus musculus with 15 samples.

How the data were processed

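Cells were sorted by flow cytometry, and RNA was taken up in TriZol and purified on RNeasy columns, per the labels. The libraries of cTEC, mTEC and skin were made with the KAPA RNA Stranded PolyA kit and those of colon and lung with the KAPA RNA HyperPrep PolyA kit. Kit and tissue are therefore confounded for colon and lung, and thymic epithelium against skin is the comparison of thymus and periphery within one kit. Each comparison of mTEC with cTEC and of lung with colon also lies within one kit. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.20, reads were aligned with STAR 2.5.1b to the mouse genome GRCm38, and expression was estimated with RSEM 1.2.28. The annotation release is not given in the sources used here.

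The deposited files hold, for each of the 15 libraries, a table of read counts per gene from the authors' alignment and a table of RSEM estimates. In the first, the deposited values are counts, in 1 unstranded and 2 stranded columns, with 4 lines of reads outside genes. In the second, the authors give the expected counts of RSEM, which divide reads that match several genes. They also give TPM and FPKM per the submitters' processing notes, and a length and an effective length of each gene in bases, as deposited. The counts of the sense column were used, since its total was 8.43 to 19.3 times that of the opposite column. Estimated counts were an alternative and the source of transcript length, and TPM and FPKM were not used here. The read counting keeps reads at a single place, so reads shared by paralogs such as the H2 genes are lost from it. Reads in PCR-amplified libraries without molecular identifiers are not independent molecules.

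The tables list 50600 genes. Symbols, coordinates and biotypes were taken from GENCODE M21 on GRCm38, which holds 50376 of these identifiers, 45737 of them in the same version, and 224 had no match. The chi-square per degree of freedom between replicates of a group ran from 20.5 to 191. Reads were scaled with TMM factors in edgeR 4.0.16, and genes with low counts were removed by filterByExpr by group, which left 19107 genes. The common biological coefficient of variation was 28.1%. One model with a term for each of the 5 groups was fitted to all 15 libraries, so that the spread is shared by the groups.

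Genes were tested with the edgeR quasi-likelihood F-test, with Benjamini-Hochberg adjustment over the genes tested, and called at an adjusted p under 0.05. The 4 main comparisons were thymic epithelium with the 3 extrathymic groups, thymic epithelium with skin, mTEC with cTEC and lung with colon. The 6 pairs of mTEC or cTEC with skin, colon or lung came from the same fit. A thymic value is the mean of the log2 levels of cTEC and mTEC, and an extrathymic value is that of skin, colon and lung. The standard error of a log2 fold change is its size divided by the square root of F. CPM in the text use gene reads scaled with the TMM factors, and log2 CPM used a prior count of 2. Shares of Gm42418 are of unscaled gene reads. A fold against a group without reads was computed with that group at 3 reads over its libraries and is given as a lower bound.

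A set of 26 gene lists with 427 genes was fixed beforehand. Of these genes 425 were found in the tables and 2, Spt1 and Ahsp, were not. The lists cover MHC class I presentation, non-classical MHC class I, regulators of MHC class I transcription, MHC class II presentation, interferon-stimulated genes, interferons and their receptors, the constitutive proteasome core, and the NF-kB and TNF receptor family. They cover markers of cortical and medullary thymic epithelium, AIRE-dependent tissue antigens, and markers of tuft cells, of skin, colon and lung epithelium and of epithelium in general. Markers of cells that a sort might not remove were those of thymocytes and T cells, B cells, myeloid cells, endothelial cells, fibroblasts, erythroid cells and melanocytes. The dissociation response, the cell cycle and autophagy complete them. Some genes stand in more than 1 list, namely Nlrc5, Rela, Nfkb1, Ctss, Tnfrsf11a, Cd40, Krt5 and Krt14. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and in the pairs over 12 tests of 2 lists. Camera with an estimated correlation and fry were run beside it.

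Genes were named by a fixed rule. In each main comparison it took the 6 largest positive and 6 largest negative log2 fold changes with adjusted p under 0.05. These needed a mean of at least 10 CPM on the higher side, at least 10 reads on the lower side, no overlap of libraries and a symbol other than a clone or pseudogene name. From each list it took up to 2 members per direction with the smallest p, and 22 genes of MHC class I, interferon and thymic biology were to be named throughout. A few genes that the rule names are not reported here. Where 5 or fewer members of a list passed in a direction, further members were named after their values were seen. The contrasts, statistical tests, lists, naming rule and alternatives were set before the data were examined, apart from 4 alternatives stated among the results that depend on processing.

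Groups share replicate numbers in the labels, so pairing was checked by correlating deviations from the group mean between libraries of different groups. Between cTEC and mTEC the same number gave 0.16 to 0.29 and different numbers gave -0.22 to -0.04. The own number was the best match in 6 of 6 libraries. In no other pair of groups was it the best match in more than 3 of 6. The sources used here do not say whether cTEC and mTEC of a number came from the same mice. The comparison of mTEC with cTEC was therefore also fitted with the replicate number as a block. In the fit of all 15 libraries the replicate effect is shared by all 5 groups. Only the fit to the thymic libraries alone pairs cTEC with mTEC.

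The pipeline was tested on simulated data with the dispersions of these counts and 1 common mean per gene over the groups compared. In each comparison 200 genes were changed by a known factor, in equal numbers up and down, and the MHC class I list was raised 2-fold. Of genes changed 2-fold, 51% were recovered for mTEC with cTEC, 82% for thymus with periphery, 63% for thymus with skin and 57% for lung with colon. Of genes changed 4-fold, 88%, 97%, 95% and 93% were recovered in the same order. Unchanged genes made up 7.93%, 6.67%, 3.31% and 5.33% of the calls. The changed list was found and 0 of 25 other lists were called. Genes were drawn independently in the simulation, whereas the estimated correlation within a real list reached 0.745 for cell cycle genes. It therefore does not show how often lists of correlated genes are called wrongly. The real comparisons called 4714 to 12268 of 19107 genes, so the simulation also does not test the scaling of libraries that differ in so many genes. Genes detected were counted after thinning each library to 12946533 gene reads with a fixed seed, and group means were compared with an exact permutation test on 3 against 3 libraries. The other versions were R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

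Alternatives covered DESeq2 size factors, upper quartile scaling, no filter, a filter at 1 CPM in 3 libraries, DESeq2, estimated counts, unstranded counts, a replicate block, counts thinned to the smallest total, a test against a 2-fold change, fits to the compared groups alone and leaving out each of the 15 libraries. Sequence reads were not analysed here.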

Results

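RNA sequencing was carried out on epithelial cells sorted by flow cytometry from male C57BL/6J mice aged 8 weeks. The 5 groups were cortical thymic epithelial cells (cTEC), medullary thymic epithelial cells (mTEC) and epithelial cells of skin, colon and lung, with 3 libraries each. Every library was a pool of cells from 5 mice, so that n = 3 pools per group throughout and each SD is the spread among pools. The series was made to look for mechanisms behind the different amounts of MHC class I on these epithelia. MHC class I molecules show peptides from inside a cell to CD8 T cells, and thymic epithelium shows them to developing T cells.

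The reads assigned to genes numbered 17864005, 16377119 and 14329113 in cTEC replicates 1 to 3 and 16015605, 15696678 and 18538657 in mTEC. Skin had 12946533, 13035361 and 15292850, colon 24555850, 32410992 and 24223316, and lung 38584035, 41978665 and 38561052. The largest library was 3.242 times the smallest. The cTEC, mTEC and skin libraries were made with one kit and the colon and lung libraries with another, so kit and tissue cannot be told apart for colon and lung. Reads in no gene, in several genes or at several places made up 24.2% to 46.9% of a library together with unmapped reads. Levels are given in CPM, counts of gene reads scaled to library size with TMM factors.

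Across genes, the correlation of log2 CPM was 0.920 to 0.991 within a group, 0.883 to 0.947 between cTEC and mTEC and 0.709 to 0.811 between thymic and extrathymic libraries. Between the extrathymic groups it was 0.729 to 0.774. Genes are not independent replicates in these correlations. The repeat-derived transcript Gm42418 took 14.8% of the gene reads of skin replicate 1, 4.89% in skin replicate 2 and 2.18% in skin replicate 3. In the 12 other libraries its share was 0.979% to 2.62%.

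The first question was how the genes of MHC class I presentation differed among the 5 epithelia. H2-K1 and H2-D1, which encode classical heavy chains, were high in both thymic groups, intermediate in skin and lower in colon and lung. H2-K1 stood at 3956 ± 335 CPM (SD, n = 3) in cTEC, 4244 ± 276 in mTEC, 2174 ± 760 in skin, 486 ± 16.1 in colon and 573 ± 74.0 in lung. B2m, which encodes their shared light chain, stood at 3347 ± 634, 3720 ± 447, 1110 ± 292, 267 ± 26.7 and 1024 ± 138 CPM in the same order. Tap1, a subunit of the transporter that brings peptides into the endoplasmic reticulum, stood at 375 ± 45.1, 324 ± 26.6, 158 ± 41.9, 18.6 ± 4.95 and 29.6 ± 3.70 CPM. Psmb9, a catalytic subunit of the immunoproteasome, reached 266 ± 45.4 CPM in cTEC, 114 ± 7.15 in mTEC and 33.0 ± 10.1 in skin, against 8.68 ± 1.39 in colon and 8.46 ± 1.71 in lung. Nlrc5, the transactivator of MHC class I genes, followed another order, with 177 ± 58.5 CPM in skin, 121 ± 18.6 in mTEC, 68.3 ± 8.03 in cTEC, 1.80 ± 0.977 in lung and 1.03 ± 0.0429 in colon.

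All 17 genes of the fixed MHC class I list differed among the 5 groups in the F-test on 4 degrees of freedom, the largest adjusted p being 0.00667. The count adjusted over the list alone was also 17. Of all 19107 genes tested, 17313 passed the same test. On GRCm38, H2-K1 is the protein-coding gene ENSMUSG00000061232.15 on chromosome 17, 33996017 to 34000347, minus strand, and H2-D1 is ENSMUSG00000073411.11 on chromosome 17, 35262730 to 35267499, plus strand. B2m is ENSMUSG00000060802.8 on chromosome 2, 122147686 to 122153083, plus strand, Nlrc5 is ENSMUSG00000074151.13 on chromosome 8, 94434356 to 94527272, plus strand and Psmb9 is ENSMUSG00000096727.2 on chromosome 17, 34181987 to 34187764, minus strand. Reads that match several H2 genes equally well are dropped by the read counting, so the levels of H2-K1, H2-D1 and the non-classical H2 genes are uncertain.

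**Figure D1:**
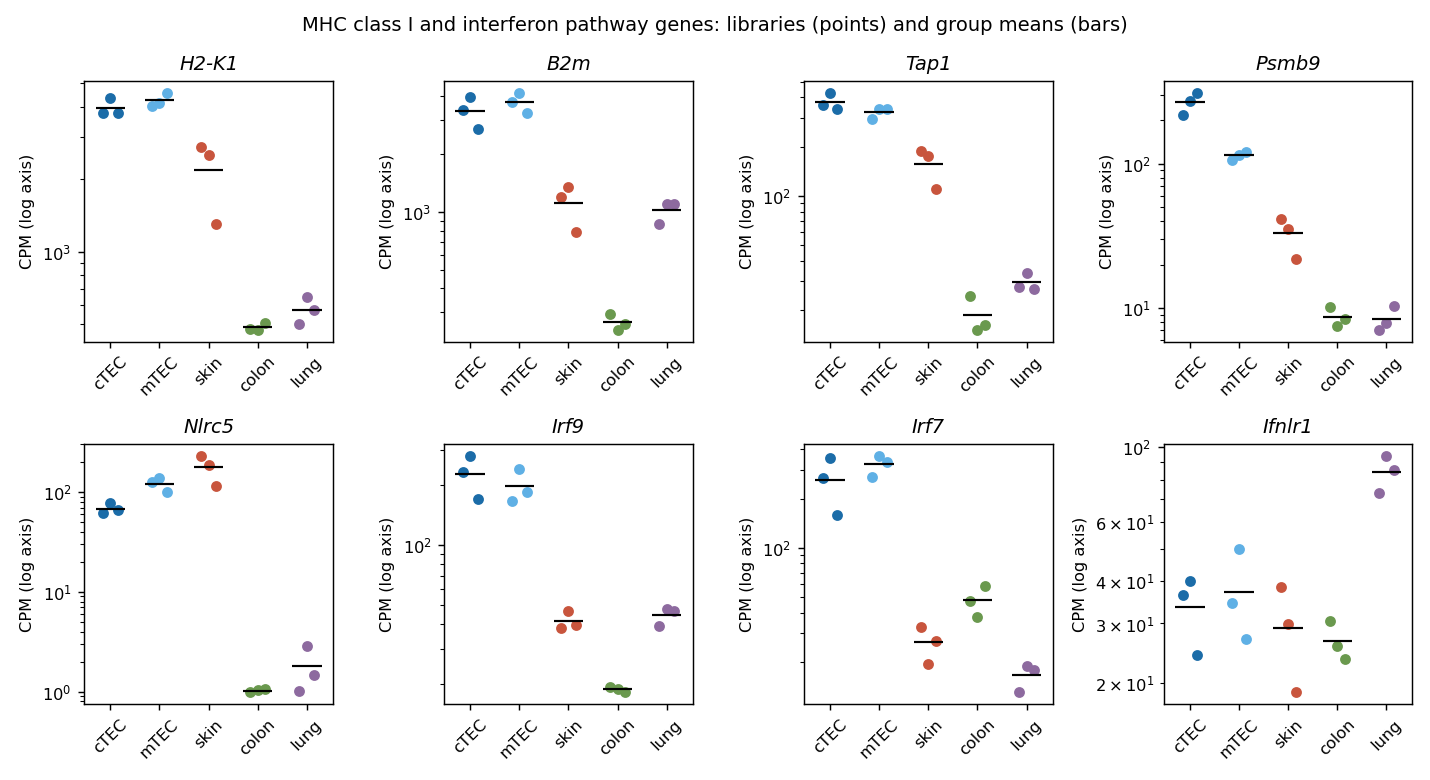
Levels of 8 genes of MHC class I presentation and interferon signalling in the 5 epithelia, in CPM on a log axis, where points are libraries (pools of 5 mice) and bars are group means of 3 libraries. H2-K1, B2m, Tap1, Psmb9, Irf9 and Irf7 stand higher in cTEC and mTEC than in the other 3 groups. The mean of Nlrc5 is highest in skin (177 CPM) and that of Ifnlr1 in lung (84.2 CPM).

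The comparison of thymic epithelium (cTEC and mTEC) with the 3 extrathymic groups asked which genes went with the higher MHC class I of the thymus. MHC class I genes were higher in thymic epithelium. H2-K1 was 4.84 times higher (log2 fold change 2.28 ± 0.16, adjusted p = 1.04e-08; ± gives the standard error of a log2 fold change). H2-D1 was 3.57 times higher (1.84 ± 0.14, adjusted p = 2.45e-08) and B2m 5.25 times (2.39 ± 0.15, adjusted p = 3.78e-09). The transporter genes Tap1 and Tap2 were 7.88 and 5.40 times higher, and Tapbp, which loads peptides, 2.30 times. The immunoproteasome genes Psmb8, Psmb9 and Psmb10 were 6.19, 13 and 7.37 times higher, with log2 fold changes of 2.63 ± 0.17, 3.70 ± 0.14 and 2.88 ± 0.14. Nlrc5 was 13.1 times higher (3.71 ± 0.20, adjusted p = 7.69e-10) over the mean of the 3 extrathymic groups. Its mean in skin was nevertheless above those of both thymic groups. Skin and mTEC libraries overlapped, with 115 CPM in skin replicate 3 against 125 and 137 CPM in mTEC replicates 1 and 2. Of the 17 listed genes 14 were higher, 2 did not pass and Canx, which encodes the chaperone calnexin, was lower (-1.03 ± 0.10, adjusted p = 4.36e-07). The counts adjusted over the list alone were 14 and 1. As a set the list was higher (median log2 fold change 1.84, adjusted p = 1.43e-04, and adjusted p = 0.20 with an estimated correlation).

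Genes induced by interferon were also higher in thymic epithelium. All 37 listed interferon-stimulated genes passed, 37 also when adjusted over the list alone (median log2 fold change 4.16, adjusted p = 2.87e-13, and adjusted p = 0.233 with an estimated correlation). Oasl2 was 47.3 times higher (5.56 ± 0.19, adjusted p = 1.51e-11) and Ifi35 5.17 times (2.37 ± 0.09, adjusted p = 2.78e-11). Stat2, a signal transducer gene, was 5.97 times higher (2.58 ± 0.14). The interferon regulatory factors Irf7, Irf9 and Irf1 were 10.6, 6.54 and 4.51 times higher (3.41 ± 0.18, 2.71 ± 0.12 and 2.17 ± 0.19). Transcripts of the type III interferons Ifnl2 and Ifnl3 gave 20 and 30 reads in cTEC and 98 and 75 in mTEC over 3 libraries each, and no read in the 9 extrathymic libraries. Against a floor of 3 reads over each group they were at least 16.3-fold and 17.9-fold higher. Ifnb1, a type I interferon gene, gave 46 reads in mTEC, 2 in cTEC and 5 in lung, too few to be tested. Ifnlr1, which encodes a chain of the type III interferon receptor, stood at 84.2 ± 10.8 CPM in lung and 26.6 to 37.1 CPM in the other groups, and did not pass (-0.19 ± 0.17, adjusted p = 0.367). Of the 11 measured genes of the list of interferons and their receptors 6 were higher and 1, Ifngr1, lower (-0.91 ± 0.16, adjusted p = 1.96e-04), and the list did not pass as a set (adjusted p = 0.160).

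MHC class II genes, whose products show peptides to CD4 T cells, were higher for 12 of 12 genes, 12 also when adjusted over the list alone (median log2 fold change 7.24, adjusted p = 2.93e-07, and adjusted p = 0.130 with an estimated correlation). H2-Ab1 and H2-Eb1, which encode chains of the class II dimer, had log2 fold changes of 7.74 ± 0.22 and 7.34 ± 0.21. Of the 17 non-classical MHC class I genes 16 were higher, as were 16 when adjusted over the list alone (median log2 fold change 2.76, adjusted p = 2.46e-05, and adjusted p = 0.130 with an estimated correlation), among them H2-T23 (2.76 ± 0.10, adjusted p = 1.64e-11). H2-M2 gave no read in one extrathymic group and was at least 446-fold higher. Among the 19 regulators of MHC class I transcription 11 were higher, such as Irf8 (4.49 ± 0.14, adjusted p = 5.49e-12), and 4 were lower (Ezh2, Nfyb, Suz12 and Eed). Ezh2, Suz12 and Eed encode a complex that represses chromatin, and Ezh2 had a log2 fold change of -0.80 ± 0.14. That list did not pass as a set (adjusted p = 0.0581), nor did the constitutive proteasome (adjusted p = 0.227), with 8 of 14 genes higher, such as Psma7 (0.56 ± 0.09), and Psmb7 lower (-0.21 ± 0.08, adjusted p = 0.0292). The call of Psmb7 was lost without cTEC replicates 1 or 3, mTEC replicates 1, 2 or 3, skin replicate 3, colon replicates 1 or 2 or lung replicate 3 (adjusted p 0.0552 to 0.114) and with DESeq2 size factors, upper quartile scaling, no filter, a filter at 1 CPM, DESeq2 and thinning. Of 16 genes of the NF-kB and TNF receptor family 12 were higher, such as Cd40, 64.0 times (6.00 ± 0.36, adjusted p = 2.43e-09), and the NF-kB inhibitor Tnfaip3 was lower (-0.79 ± 0.21). That set was higher (median log2 fold change 1.08, adjusted p = 0.00427, and adjusted p = 0.332 with an estimated correlation).

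Genes of thymic identity were higher in the thymic libraries. Foxn1, the regulator that makes thymic epithelium, stood at 192 ± 53.5 CPM in cTEC, 126 ± 24.1 in mTEC, 24.8 ± 5.16 in skin and 3.41 and 0.112 in colon and lung. Fezf2, a regulator of tissue antigens in mTEC, gave no read in colon and lung and was at least 1427-fold higher in thymic epithelium. The milk protein gene Csn2 was at least 1400-fold higher. Pax1, a pharyngeal pouch regulator, stood at 718 ± 142 CPM in cTEC and 214 ± 42.5 in mTEC, against 1.22, 0.0149 and 0.225 in skin, colon and lung. Tbata stood at 1367 and 338 CPM in cTEC and mTEC against 0.617, 0.0298 and 2.26, and Slc46a2 at 540 and 260 against 8.96, 0.0111 and 0.0398. Cortical markers were higher for 13 of 15 genes (median log2 fold change 4.04, adjusted p = 9.77e-05, and adjusted p = 0.154 with an estimated correlation), including the T cell growth factor Il7 (6.01 ± 0.19), and lower for Trpm4 (-1.86 ± 0.14) and Kitl (-1.12 ± 0.16). Medullary markers were higher for 14 of 17 (median log2 fold change 4.06, adjusted p = 3.56e-04, and adjusted p = 0.130 with an estimated correlation) and lower for Cldn4 (-1.97 ± 0.22) and Cldn3 (-1.09 ± 0.18). Of 18 measured AIRE-dependent tissue antigens 15 were higher (median log2 fold change 4.88, adjusted p = 1.26e-04, and adjusted p = 0.237 with an estimated correlation), with a median of 3.59 when groups without reads were set to the floor. Crp among them was at least 234-fold higher, and the myelin gene Mbp was lower (-1.56 ± 0.13). Tuft cell markers were higher for 12 of 14 genes (median log2 fold change 4.98, adjusted p = 7.62e-04, and adjusted p = 0.326 with an estimated correlation; median 4.59 at the floor), such as the ion channel gene Trpm5 (6.72 ± 0.35), and lower for L1cam (-2.24 ± 0.21) and Ptgs1 (-0.66 ± 0.16). The counts adjusted over the list alone were the same for these 4 lists.

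Among the largest differences in the other direction, Slc6a14, an amino acid transporter gene, was 133 times lower in thymic epithelium (log2 fold change -7.05 ± 0.45, adjusted p = 4.76e-09). Nipal1 was 119 times lower and Ttll7 109 times lower (-6.90 ± 0.31 and -6.77 ± 0.25). Lgals3, which encodes galectin-3, stood at 1762 ± 688 CPM in skin and 1437 ± 342 in colon against 9.30 ± 4.11 in cTEC, and was 107 times lower. The growth factor gene Areg was 69.2 times lower and Scel, of the cornified envelope, 67.0 times (-6.11 ± 0.23 and -6.07 ± 0.24). Lung epithelium markers were lower for 6 of 19 genes and higher for 2 (median log2 fold change -1.13, adjusted p = 0.0162, and adjusted p = 0.407 with an estimated correlation). This median was smaller in size without skin replicate 1. Hopx, of alveolar cells, was lower (-5.19 ± 0.30), and the ciliated cell regulator Foxj1 was higher (2.53 ± 0.26). Skin markers (7 higher, 3 lower of 19, adjusted p = 0.706), colon markers (8 and 8 of 20, adjusted p = 0.0717) and pan-epithelial markers (4 and 10 of 16, adjusted p = 0.0581) did not pass as sets. The keratin gene Krt18 was higher (3.40 ± 0.17) and the splicing regulator gene Esrp2 lower (-1.72 ± 0.09). Counts adjusted over the list alone were the same for these 4 lists.

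Markers of other cell types moved along with these groups. Thymocyte and T cell markers were higher in thymic libraries for 19 of 20 genes (median log2 fold change 4.24, adjusted p = 2.36e-06, and adjusted p = 0.20 with an estimated correlation; median 3.79 at the floor), with Cd8a at a log2 fold change of 6.44 ± 0.45. B cell markers were higher for 6 of 8, or 8 when adjusted over the list alone (median log2 fold change 3.97, adjusted p = 0.00388, and adjusted p = 0.310 with an estimated correlation; median 3.96 at the floor), such as Ighm (4.83 ± 0.40). Myeloid markers were higher for 10 of 17 (median log2 fold change 1.01, adjusted p = 0.0334, and adjusted p = 0.465 with an estimated correlation), such as Mpeg1 (3.21 ± 0.33), and Csf1r was lower (-1.60 ± 0.31). That call was lost without skin replicate 2 (adjusted p = 0.0641). Endothelial markers were lower for 12 of 12 (median log2 fold change -3.04, adjusted p = 1.80e-04, and adjusted p = 0.332 with an estimated correlation), such as Emcn (-4.84 ± 0.52), and fibroblast markers for 10 of 12 (median log2 fold change -3.47, adjusted p = 1.80e-04, and adjusted p = 0.332 with an estimated correlation), such as Dpt (-4.65 ± 0.39). Cell cycle genes were lower for 7 of 20 (median log2 fold change -0.53, adjusted p = 0.0432, and adjusted p = 0.648 with an estimated correlation), such as Tyms (-0.74 ± 0.16), a call lost without cTEC replicate 2, mTEC replicate 2 or skin replicate 3 (adjusted p 0.0518 to 0.0916), with the filter at 1 CPM and with fry. Its median was -0.21 without skin replicate 3. The endothelial, fibroblast and cell cycle lists did not set the thymic libraries apart from every extrathymic group. Endothelial totals were 14.3 to 42.7 CPM in thymic libraries, 15.2 to 55.8 in colon and 122 to 450 in skin and lung. Fibroblast totals were 273 to 568, 235 to 537 and 1306 to 8346 CPM in the same order. Cell cycle totals in lung, 123 to 133 CPM, lay below those of all thymic libraries, 167 to 505 CPM. Erythroid markers (2 higher, 4 lower of 6, adjusted p = 0.0936), melanocyte markers (2 and 1 of 5, adjusted p = 0.816), dissociation response genes (11 and 2 of 18, adjusted p = 0.166) and autophagy genes (4 and 11 of 21, adjusted p = 0.0581) did not pass as sets. Hbb-bs, a haemoglobin gene, was lower (-5.77 ± 0.40), and the autophagosome gene Map1lc3b was higher (0.94 ± 0.12). The counts of these lists adjusted over the list alone were otherwise the same.

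A total of 12268 of 19107 genes differed between thymic and extrathymic epithelium, 7122 higher and 5146 lower in the thymus. Of the 26 lists 16 passed with the preset correlation and 0 with an estimated correlation, whereas fry, which asks whether genes move one way on balance, called 24. The fold is taken between means of group log levels and includes the kit difference of colon and lung. Against a threshold of a 2-fold change 5684 genes passed, and upper quartile scaling raised the median log2 fold change of all genes from 0.14 to 0.30 and that of the MHC class I list from 1.84 to 1.99.

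The comparison of thymic epithelium with skin asked the same question within one kit. MHC class I genes were higher in the thymus than in skin. H2-K1 was 1.89 times higher (log2 fold change 0.91 ± 0.22, adjusted p = 0.00221), H2-D1 1.72 times (0.79 ± 0.19, adjusted p = 0.00250) and B2m 3.18 times (1.67 ± 0.22, adjusted p = 1.28e-05). The immunoproteasome genes Psmb8, Psmb9 and Psmb10 were 2.32, 5.30 and 10.1 times higher, and Tap1, Tap2 and Tapbp 2.21, 2.94 and 2.22 times. Nlrc5 went the other way and was 1.95 times lower in thymic epithelium (-0.96 ± 0.23, adjusted p = 0.00256). Of the 17 listed genes 14 were higher, 1 lower and 2 did not pass, also when adjusted over the list alone (median log2 fold change 1.15, adjusted p = 0.00718, and adjusted p = 0.294 with an estimated correlation). Beside these genes, skin replicate 1 carried the 14.8% of Gm42418 reads, and without it H2-K1 stood at a log2 fold change of 1.10 and Nlrc5 at -0.73, both with adjusted p under 0.05.

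**Figure D2:**
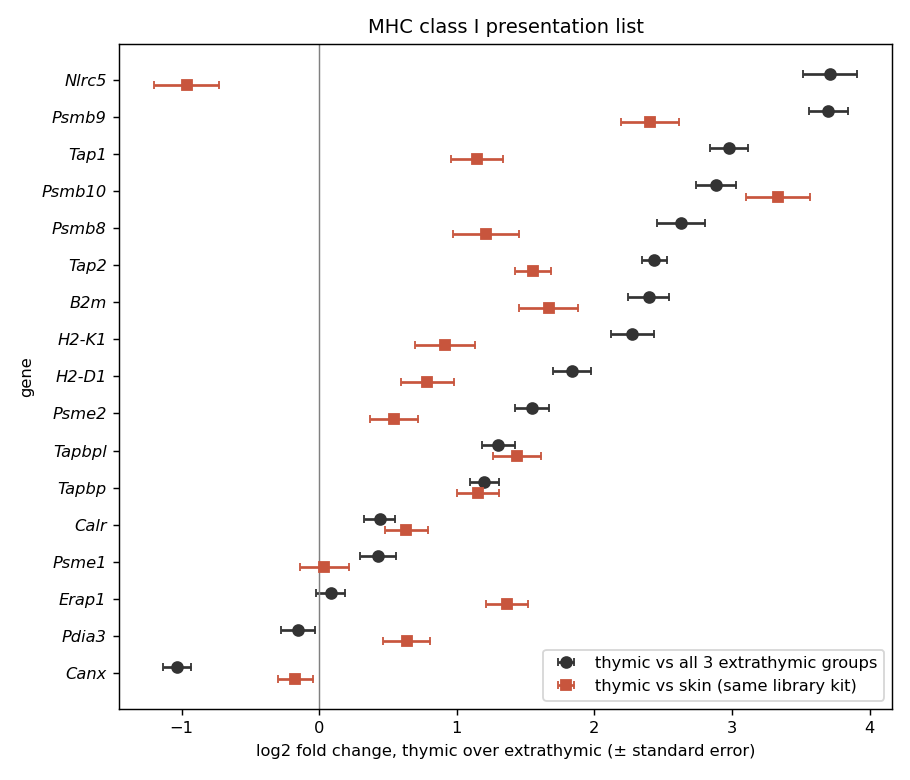
Log2 fold changes of the 17 MHC class I genes, higher in thymic epithelium to the right of 0, with bars of 1 standard error. Black circles compare thymic epithelium with all 3 extrathymic groups and red squares with skin, and Nlrc5 lies at 3.71 ± 0.20 in the first and -0.96 ± 0.23 in the second.

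Interferon-stimulated genes were higher than in skin for 37 of 37 genes, also when adjusted over the list alone (median log2 fold change 4.44, adjusted p = 6.14e-12, and adjusted p = 0.288 with an estimated correlation), such as Ddx58, a sensor of viral RNA (3.11 ± 0.18). Irf7 was 11.1 times higher (3.47 ± 0.28, adjusted p = 1.37e-07), and Stat2, Irf9 and Irf1 4.32, 5.13 and 3.08 times. Ifnl2 and Ifnl3 were at least 9.51-fold and 10.5-fold higher, and Ifnlr1 did not pass (0.29 ± 0.24, adjusted p = 0.310). Interferons and receptors had 6 genes higher, such as Il10rb (2.46 ± 0.11), and Ifngr1 lower (adjusted p of the list 0.0748). MHC class II genes were higher for 12 of 12 (median log2 fold change 7.16, adjusted p = 1.26e-06, and adjusted p = 0.156 with an estimated correlation), and Ciita, their transactivator, was 431 times higher (8.75 ± 0.58, adjusted p = 1.80e-08). Non-classical MHC class I genes were higher for 16 of 17 (median log2 fold change 2.48, adjusted p = 2.14e-04, and adjusted p = 0.156 with an estimated correlation), such as H2-M2 (4.59 ± 0.33). Regulators of MHC class I transcription had 11 higher and 5 lower genes (Ezh2, Nfyb, Rela, Nlrc5 and Nfyc; adjusted p = 0.387), and NF-kB genes 9 and 3 (Tnfaip3, Rela and Nfkbia; adjusted p = 0.165). The constitutive proteasome had Psma7 and Psma4 higher and Psmb5, Psmb3, Psmb7 and Psmb2 lower (adjusted p = 0.218). The call of Psma7 was lost without skin replicate 1 (adjusted p = 0.0946) and that of Psma4 without skin replicates 1 or 2 (adjusted p 0.0527 to 0.150), and both were lost with the compared groups alone. Counts adjusted over the list alone were the same here, except 10 higher NF-kB genes.

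Among the named genes with the largest differences from skin, Tbata was 1191 times higher (10.22 ± 0.64, adjusted p = 1.07e-08), Wfikkn2 620 times, the lymphoid chemokine gene Ccl21a 472 times, Dpp6 382 times and the interferon-induced GTPase gene Tgtp2 364 times. Krt1, a keratin gene of the cornifying epidermis, stood at 5194 ± 1845 CPM in skin and 4.81 and 11.7 in cTEC and mTEC (log2 fold change -9.44 ± 0.42, adjusted p = 4.76e-10). Calm5 (-10.07 ± 0.52), Ndufa4l2 (-9.36 ± 0.38) and the ceramidase gene Acer1 (-9.34 ± 0.40) were lower too. The homeobox gene Msx2 stood at 42.1 ± 62.9 CPM in skin against 0.183 in mTEC, and the receptor gene Il20ra at 50.9 ± 32.1 against 0.284, each with 1 read in cTEC. Skin markers were lower for 16 of 19 (median log2 fold change -5.35, adjusted p = 2.70e-09, and adjusted p = 0.156 with an estimated correlation), such as Krt10 (-8.47 ± 0.31). Cortical markers were higher for 14 of 15 (median log2 fold change 4.09, adjusted p = 5.10e-05, and adjusted p = 0.156 with an estimated correlation) with Psmb11, the thymus-specific proteasome subunit, at 332 ± 226 CPM in cTEC, 19.2 ± 7.98 in mTEC and 3 reads over the skin libraries. AIRE-dependent antigens were higher for 14 of 18 (median log2 fold change 7.61, adjusted p = 5.10e-05, and adjusted p = 0.288 with an estimated correlation; median 4.79 at the floor), and Aire itself had a log2 fold change of 7.61 ± 0.67. Colon markers were higher for 10 of 20 and lower for Guca2a and Lgr5 (median log2 fold change 3.14, adjusted p = 0.0468, and adjusted p = 0.502 with an estimated correlation; median 1.48 at the floor), a call lost without cTEC replicates 1 or 3, mTEC replicate 1 or skin replicates 2 or 3 (adjusted p 0.0557 to 0.159). It was also lost with DESeq2 size factors, with upper quartile scaling and on thinned counts. Medullary (11 higher, 6 lower of 17, adjusted p = 0.264), tuft (10 and 3 of 14, adjusted p = 0.0748), lung (8 and 2 of 19, adjusted p = 0.165) and pan-epithelial markers (8 and 5 of 16, adjusted p = 0.693) did not pass as sets. The counts adjusted over the list alone differed only in 9 higher pan-epithelial genes.

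Markers of other cells and states moved as well between thymic epithelium and skin. Thymocyte and T cell markers were higher for 17 of 20 (median log2 fold change 5.06, adjusted p = 1.39e-04, and adjusted p = 0.288 with an estimated correlation; median 3.96 at the floor), with Bcl11b, which keratinocytes also express, lower (-3.07 ± 0.37). B cell markers were higher for 7 of 8 (median log2 fold change 4.55, adjusted p = 0.0164, and adjusted p = 0.331 with an estimated correlation; median 3.34 at the floor). Endothelial (median log2 fold change -4.28, adjusted p = 3.59e-06, and adjusted p = 0.288 with an estimated correlation) and fibroblast markers (median log2 fold change -4.03, adjusted p = 3.59e-06, and adjusted p = 0.288 with an estimated correlation) were lower for 12 of 12 genes each, such as Egfl7 (-4.71 ± 0.47) and Col1a1 (-6.61 ± 0.46). Erythroid markers were lower for 4 of 6 (Hbb-bs, Hba-a1, Hbb-bt and Hba-a2; median log2 fold change -5.46, adjusted p = 0.00461, and adjusted p = 0.288 with an estimated correlation) and cell cycle genes for 20 of 20 (median log2 fold change -2.0, adjusted p = 2.34e-05, and adjusted p = 0.429 with an estimated correlation), such as Ube2c (-2.75 ± 0.27). The cell cycle totals were 433, 618 and 1703 CPM in skin replicates 1 to 3, 505, 380 and 472 CPM in mTEC and 243, 191 and 167 CPM in cTEC. Skin replicate 3 thus carried much of this difference, and the median was smaller in size without it. Myeloid markers (5 higher and 4 lower of 17, adjusted p = 0.707), melanocyte markers (Dct lower of 5, adjusted p = 0.260), dissociation response genes (5 and 3 of 18, adjusted p = 0.458) and autophagy genes (3 and 7 of 21, adjusted p = 0.188) did not pass as sets. Adjusted over the list alone, 4 dissociation genes were higher and the other counts were the same. A total of 11695 genes differed, 6811 higher and 4884 lower in the thymus, and 14 of 26 lists passed with the preset correlation, 0 with an estimated correlation and 23 with fry. Against a threshold of a 2-fold change 6108 genes passed.

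Each thymic type was also compared with each extrathymic epithelium. The MHC class I list was higher in all 6 pairs. Against skin its median log2 fold change was 1.01 for mTEC (adjusted p = 0.00237, and adjusted p = 0.149 with an estimated correlation) and 1.21 for cTEC (adjusted p = 0.00521, and adjusted p = 0.168 with an estimated correlation). Against colon it was 2.15 for mTEC and 2.13 for cTEC (adjusted p = 4.57e-04 for both). Against lung it was 2.01 for mTEC (adjusted p = 4.57e-04) and 1.95 for cTEC (adjusted p = 2.17e-04). In the colon and lung pairs the adjusted p was 0.145 with an estimated correlation. H2-K1 was 8.73 and 8.13 times higher in mTEC and cTEC than in colon, and 7.41 and 6.90 times higher than in lung. Psmb9 was 30.7 times higher in cTEC than in colon and 31.5 times higher than in lung (4.94 ± 0.25 and 4.98 ± 0.25). Nlrc5 was lower in cTEC than in skin (-1.38 ± 0.28, adjusted p = 8.65e-04), and the mTEC value did not pass (-0.55 ± 0.28, adjusted p = 0.104). Ifnlr1 was lower in mTEC and cTEC than in lung (-1.18 ± 0.27 and -1.33 ± 0.27) and did not pass in the 4 pairs with skin and colon.

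The comparison of mTEC with cTEC asked how the 2 thymic types differ, both made with one kit. MHC class I heavy and light chain genes did not pass between them, in a test whose spread is shared by all 5 groups. Their log2 fold changes were 0.10 ± 0.24 for H2-K1, 0.07 ± 0.21 for H2-D1 and 0.15 ± 0.23 for B2m (adjusted p = 0.798, 0.850 and 0.673). Psmb9 was 2.34 times lower in mTEC (-1.22 ± 0.22, adjusted p = 0.00138), and Tap2 and Psmb10 were 1.37 and 1.59 times lower (-0.45 ± 0.14, adjusted p = 0.0292, and -0.67 ± 0.22, adjusted p = 0.0376). Psme1, an activator of the proteasome, was 1.84 times higher (0.88 ± 0.21, adjusted p = 0.00742), and Nlrc5 1.77 times (0.82 ± 0.28, adjusted p = 0.0442). The call of Nlrc5 was lost without cTEC replicates 1, 2 or 3 or mTEC replicates 1 or 2 (adjusted p 0.0742 to 0.114) and with estimated counts (adjusted p = 0.0669). That of Tap2 was lost without cTEC replicates 2 or 3 or mTEC replicate 1 (adjusted p 0.0809 to 0.141) and without a filter, and that of Psmb10 without cTEC replicates 2 or 3 or mTEC replicates 1 or 2 (adjusted p 0.0599 to 0.179), with DESeq2 size factors or upper quartile scaling, or without a filter. The other 12 of the 17 genes did not pass, among them Tap1 (-0.21 ± 0.21), Tapbp (-0.29 ± 0.17) and Psmb8 (0.01 ± 0.26). The counts adjusted over the list alone were 2 and 3. The list did not pass as a set (adjusted p = 0.669), its median of 0.07 and mean of 0.01 being above 0 and its test statistic below.

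Of 37 interferon-stimulated genes only Isg20, an exonuclease gene, differed between mTEC and cTEC, also when adjusted over the list alone, and it was 4.67 times lower in mTEC (-2.22 ± 0.31, adjusted p = 2.67e-04). The set did not pass (adjusted p = 0.162), though it did without cTEC replicate 3 (adjusted p = 0.00195) or mTEC replicate 2 (adjusted p = 0.00555), and with no filter (adjusted p = 0.0320). With replicates paired by number in a fit of the thymic libraries alone it did not pass (adjusted p = 0.0691). Nor did it with the block in the fit of all 15 libraries (adjusted p = 0.134). That block is shared with groups that did not match by number, so it is not a paired test of mTEC with cTEC. Stat2 (0.07 ± 0.21), Irf7 (0.32 ± 0.27), Irf9 (-0.20 ± 0.18) and Ifnlr1 (0.15 ± 0.27) did not pass, and neither did Irf1 (-0.82 ± 0.30, adjusted p = 0.0599), Ifnl2 (2.22 ± 0.72, adjusted p = 0.0553) or Ifnl3 (1.23 ± 0.62, adjusted p = 0.191). Foxn1 did not pass either (-0.61 ± 0.29, adjusted p = 0.143). In a fit to the thymic libraries alone, Irf1 and Ifnl2 passed without a block (adjusted p = 0.0302 and 0.0230) and Foxn1 did not (adjusted p = 0.0527). With replicates also paired by number, Irf1 (-0.83), Ifnl2 (2.22) and Foxn1 (-0.64) passed (adjusted p = 0.00400, 0.0120 and 0.00448). With the shared block in the fit of all 15 libraries none of them did. In the main fit Irf1 was also lower without cTEC replicate 3 (adjusted p = 0.0316). Ifngr2 and Ifngr1, of the interferon gamma receptor, were higher (1.09 ± 0.19 and 0.73 ± 0.25), and Il10rb and Ifnar2 lower (-0.86 ± 0.11 and -0.62 ± 0.21). The call of Ifngr1 was lost without cTEC replicates 1, 2 or 3 or mTEC replicates 1, 2 or 3 (adjusted p 0.0607 to 0.123) and that of Ifnar2 without cTEC replicates 1, 2 or 3 or mTEC replicates 1 or 3 (adjusted p 0.0505 to 0.178). That of Ifnar2 was also lost with DESeq2 size factors, upper quartile scaling, no filter, thinning and the block on all 15 libraries. Neither call was lost when replicates were paired by number in the thymic libraries alone. The list of interferons and receptors did not pass (adjusted p = 0.445). Of its members 3 were higher when adjusted over the list alone.

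Medullary genes were higher in mTEC and cortical genes higher in cTEC. Aire, which drives expression of tissue antigens, stood at 481 ± 207 CPM in mTEC and 44.3 ± 20.8 in cTEC, 10.9 times higher in mTEC (3.44 ± 0.51, adjusted p = 3.84e-04). It is ENSMUSG00000000731.15 on chromosome 10, 78030022 to 78043610, minus strand. Medullary markers were higher for 11 of 17, or 12 when adjusted over the list alone (median log2 fold change 1.41, adjusted p = 6.99e-04, and adjusted p = 0.137 with an estimated correlation), such as the RANK gene Tnfrsf11a (2.80 ± 0.24, adjusted p = 7.09e-06). AIRE-dependent antigens were higher for 14 of 18, or 15 when adjusted over the list alone (median log2 fold change 2.95, adjusted p = 9.57e-09, and adjusted p = 0.137 with an estimated correlation), such as Crp, 22.9 times (4.52 ± 0.34, adjusted p = 2.34e-05). Cortical markers were lower in mTEC for 11 of 15, or 12 when adjusted over the list alone (median log2 fold change -2.66, adjusted p = 6.97e-08, and adjusted p = 0.119 with an estimated correlation). Psmb11 was 17.3 times lower in mTEC (-4.11 ± 0.42, adjusted p = 3.02e-05), and Prss16, a thymus-specific serine protease gene, 19.8 times (-4.31 ± 0.52, adjusted p = 9.33e-05). Prss16 stood at 1685, 1313 and 4884 CPM in cTEC replicates 1 to 3. Psmb11 is ENSMUSG00000072423.4 on chromosome 14, 54621433 to 54629556, plus strand. Kitl was lower by a log2 fold change of -2.66 ± 0.25.

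Among the largest differences, Dlk1, a Notch family gene, was 66.8 times higher in mTEC (6.06 ± 0.80, adjusted p = 1.81e-04) and Madcam1, an addressin gene, 35.3 times (5.14 ± 0.89, adjusted p = 0.00123). The opioid precursor gene Pdyn, the cadherin gene Cdh22 and the intestinal antimicrobial gene Ang4 had log2 fold changes of 5.10 ± 0.96, 4.82 ± 0.49 and 4.65 ± 0.56. Lower in mTEC were Prss23 (-5.12 ± 0.25), Igfbp7 (-4.67 ± 0.32), the sodium channel gene Scn1a (-4.48 ± 0.40), Serpinf1 (-4.21 ± 0.42) and Inmt (-4.13 ± 0.88). The regulators of MHC class I transcription had Ezh2 (1.42 ± 0.22) and Nlrc5 higher, and 2 genes lower, such as Nfkb1 (-0.81 ± 0.12; adjusted p of the list 0.408). MHC class II genes had Ctss (2.12 ± 0.37) and Ifi30 higher and H2-DMa (-1.16 ± 0.30) lower (adjusted p = 0.845). The call of H2-DMa was lost without mTEC replicate 1 (adjusted p = 0.0667). Non-classical genes had H2-Q1 (3.56 ± 0.70), H2-M2 and H2-Q10 higher (adjusted p = 0.489). NF-kB family genes had 7 higher, such as Nfkb2 (1.06 ± 0.15), and Nfkb1 and Ltbr lower, or 8 higher when adjusted over the list alone (adjusted p = 0.175). Of the constitutive proteasome Psmb4 was lower (-0.44 ± 0.13, adjusted p = 0.0259), and 0 genes when adjusted over the list alone (adjusted p of the list 0.209). That call of Psmb4 was lost without cTEC replicate 3 or mTEC replicates 1 or 2 (adjusted p 0.0619 to 0.131) and without a filter.

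Of the marker lists of other epithelia, those of colon and lung passed as higher in mTEC than in cTEC, and that of skin did not. Colon markers were higher for 13 of 20, also when adjusted over the list alone (median log2 fold change 2.22, adjusted p = 5.50e-05, and adjusted p = 0.309 with an estimated correlation; median 2.11 at the floor), such as the intestinal regulator Cdx1 (2.32 ± 0.32). Lung markers were higher for 11 of 19, or 13 when adjusted over the list alone (median log2 fold change 1.67, adjusted p = 0.0185, and adjusted p = 0.637 with an estimated correlation), such as the surfactant gene Sftpa1 (3.38 ± 0.56), and Etv5 was lower (-1.25 ± 0.33). The list call was lost without cTEC replicate 2 or mTEC replicate 3 (adjusted p 0.0531 to 0.0960), and that of Etv5 without mTEC replicates 1 or 2 (adjusted p 0.0553 to 0.0569). Skin markers were higher for 9 of 19 and did not pass as a set (adjusted p = 0.0525). With the preset correlation they did pass when replicates were paired by number in the thymic libraries alone (adjusted p = 0.0270). The same held with the block in the fit of all 15 libraries (adjusted p = 0.0397). Tuft markers passed as a set (median log2 fold change 0.79, adjusted p = 0.0294, and adjusted p = 0.637 with an estimated correlation), with Pou2f3 higher (0.88 ± 0.30, adjusted p = 0.0464) and 0 of 14 when adjusted over the list alone. The set call was lost without cTEC replicates 2 or 3 or mTEC replicate 3 (adjusted p 0.0574 to 0.182), and that of Pou2f3 without cTEC replicates 2 or 3 or mTEC replicates 1, 2 or 3 (adjusted p 0.0647 to 0.175). Pan-epithelial markers had 8 higher, such as St14 (1.13 ± 0.20), and Krt19 lower (-1.68 ± 0.45), or 9 and 3 when adjusted over the list alone (adjusted p = 0.198). The call of Krt19 was lost without cTEC replicate 2 or mTEC replicate 1 (adjusted p 0.0592 to 0.0728). Cell cycle genes were higher for 12 of 20, or 18 when adjusted over the list alone (median log2 fold change 1.47, adjusted p = 1.84e-04, and adjusted p = 0.637 with an estimated correlation), such as Cdk1 (2.40 ± 0.44).

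Markers of other cells differed between the thymic types too. Thymocyte markers were lower in mTEC for 6 of 20 (median log2 fold change -1.47, adjusted p = 5.66e-05, and adjusted p = 0.309 with an estimated correlation), such as Cd8a (-2.38 ± 0.53). B cell markers were higher for 3 of 8, such as Cd22, or 4 when adjusted over the list alone (median log2 fold change 1.68, adjusted p = 0.0294, and adjusted p = 0.637 with an estimated correlation), a call lost without cTEC replicates 2 or 3 or mTEC replicate 3 (adjusted p 0.0573 to 0.0796), on thinned counts and with the filter at 1 CPM. Myeloid markers were higher for 6 of 17, or 7 when adjusted over the list alone (median log2 fold change 1.25, adjusted p = 0.0123, and adjusted p = 0.637 with an estimated correlation), such as Marco (4.0 ± 0.67), a call lost without cTEC replicate 2 (adjusted p = 0.0573). Cd68 was lower (-0.65 ± 0.21, adjusted p = 0.0384). Its call was lost without cTEC replicates 1, 2 or 3 or mTEC replicates 1, 2 or 3 (adjusted p 0.0554 to 0.142). The same held with DESeq2 size factors, no filter, estimated counts or the block on all 15 libraries, but not with the block on thymic libraries alone. Erythroid markers were higher for 6 of 6 (median log2 fold change 2.97, adjusted p = 8.20e-04, and adjusted p = 0.309 with an estimated correlation), such as Alas2 (2.92 ± 0.60). Their levels were low, with list totals of 1.52, 0.78 and 0.336 CPM in cTEC replicates 1 to 3. The totals were 11.4, 3.96 and 9.67 CPM in mTEC replicates 1 to 3, against 63.5 to 123 CPM in skin. Dissociation response genes were lower as a set (median log2 fold change -0.32, adjusted p = 0.0294, and adjusted p = 0.663 with an estimated correlation) with Ier3 the one gene past the test (-1.20 ± 0.23), a set call lost without cTEC replicate 2 or mTEC replicates 1 or 3 (adjusted p 0.0838 to 0.311) and with fry. The median depended on single libraries, with -0.00724 and -0.53 without cTEC replicates 2 and 3, and -0.18, -0.52 and -0.23 without mTEC replicates 1, 2 and 3. Endothelial (2 higher, 1 lower of 12, adjusted p = 0.445), fibroblast (3 and 2 of 12, adjusted p = 0.858), melanocyte (1 and 1 of 5, adjusted p = 0.361) and autophagy lists (0 and 2 of 21, adjusted p = 0.209) did not pass. Counts adjusted over the list alone differed for fibroblast (4 higher), melanocyte (3 higher) and autophagy lists (1 lower).

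A total of 4714 genes differed between mTEC and cTEC, 2908 higher and 1806 lower in mTEC, and 12 of 26 lists passed with the preset correlation, 0 with an estimated correlation and 16 with fry. A fit to the thymic libraries alone gave 5659 genes without a block and 7091 with the replicate number as a block, 3924 higher and 3167 lower. The block in the fit of all 15 libraries gave 4431. With the block on thymic libraries alone, all 70 values of named genes called in the main fit kept their call. Those lost under other settings are among them. The count was 2408 without mTEC replicate 1 and 3075 without cTEC replicate 2, and without cTEC replicate 2 the lists called numbered 7. Against a threshold of a 2-fold change 1158 genes passed.

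The mean number of genes detected was highest in mTEC. With every library thinned to 12946533 gene reads, at least 1 read was found for 26234 ± 1128 genes in mTEC (SD, n = 3), 22017 ± 2236 in cTEC, 20834 ± 314 in colon, 20332 ± 70.6 in lung and 17442 ± 1256 in skin. The mTEC mean was 4217 genes above that of cTEC, with every mTEC library above every cTEC library (exact permutation test, 2-sided p = 0.1, the smallest that 3 against 3 libraries allow). The difference was 1785 genes at a minimum of 5 reads and 2025 for protein-coding genes alone. In cTEC the libraries gave 24063, 22358 and 19631 genes, and without cTEC replicate 3 the difference from mTEC was 3024.

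**Figure D3:**
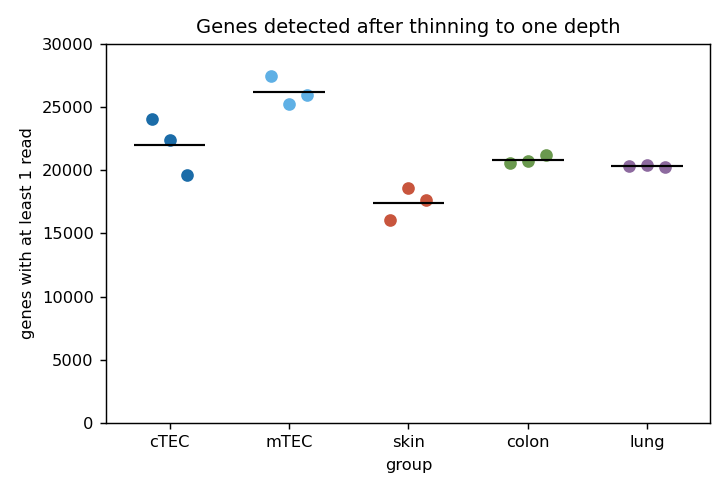
Genes with at least 1 read after every library was thinned to 12946533 gene reads, with the axis from 0. Points are libraries and bars are means of 3, which run from 17442 in skin to 26234 in mTEC.

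The comparison of lung with colon set the 2 other extrathymic epithelia side by side within one kit. Among the named genes with the largest differences, markers of lung epithelium were higher in lung. Cldn18, a claudin gene, stood at 4323 ± 200 CPM in lung and 0.331 in colon (log2 fold change 13.68 ± 0.69, adjusted p = 7.38e-10). The surfactant protein genes Sftpc and Sftpb stood at 6924 ± 3663 and 1283 ± 641 CPM in lung and at 0.657 and 0.134 in colon. The water channel gene Aqp5 (13.04 ± 0.45), Sec14l3 (12.96 ± 0.53) and the basement membrane collagen gene Col4a3 (12.90 ± 0.48) followed. Lower in lung were the mucin gene Muc2, at 7358 ± 663 CPM in colon and 0.396 in lung (log2 fold change -14.17 ± 0.72, adjusted p = 7.63e-10), and Dmbt1 (-15.27 ± 0.92). Lypd8, Mgam, Klk1 and Gpa33 had log2 fold changes of -14.15 ± 0.73, -11.87 ± 0.56, -11.84 ± 0.76 and -11.75 ± 0.59. Lung markers were higher for 18 of 19 (median log2 fold change 12.38, adjusted p = 7.72e-11, and adjusted p = 0.177 with an estimated correlation), and colon markers lower for 20 of 20 (median log2 fold change -10.93, adjusted p = 1.70e-13, and adjusted p = 0.0778 with an estimated correlation; median -10.56 at the floor). Pan-epithelial markers were lower for 12 of 16 (median log2 fold change -1.43, adjusted p = 0.0105, and adjusted p = 0.478 with an estimated correlation), such as Epcam (-3.57 ± 0.22), and higher for Krt7 (2.43 ± 0.18) and Prss8 (1.04 ± 0.17). Counts adjusted over the list alone were the same for these 3 lists.

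Some MHC class I genes differed between lung and colon. B2m was 3.84 times higher in lung (1.94 ± 0.24, adjusted p = 5.94e-06) and Tap2 and Tapbp 2.42 and 2.47 times (1.27 ± 0.14 and 1.30 ± 0.17), while Psmb10 was 3.30 times lower (-1.72 ± 0.23, adjusted p = 1.28e-05). H2-D1 and Tap1 were higher (0.54 ± 0.21, adjusted p = 0.0393, and 0.67 ± 0.21, adjusted p = 0.0145). H2-K1 (0.24 ± 0.24), Psmb8 (0.59 ± 0.27), Psmb9 (-0.04 ± 0.22) and Nlrc5 (0.81 ± 0.36) did not pass. The call of H2-D1 was lost without colon replicates 1, 2 or 3 or lung replicates 2 or 3 (adjusted p 0.0806 to 0.121) and on thinned counts, and that of Tap1 without colon replicates 2 or 3 or lung replicate 2 (adjusted p 0.0628 to 0.0807). Of 17 genes 6 were higher and 3 lower (Psmb10, Erap1 and Canx), also when adjusted over the list alone, and the list did not pass (adjusted p = 0.615). The call of Erap1 (-0.47 ± 0.16, adjusted p = 0.0228) was lost without colon replicate 1 or lung replicates 1, 2 or 3 (adjusted p 0.0576 to 0.0789). Interferon-stimulated genes were higher in lung for 25 of 37 and lower for 7, also when adjusted over the list alone (median log2 fold change 1.76, adjusted p = 0.00865, and adjusted p = 0.941 with an estimated correlation), such as Usp18 (5.41 ± 0.37) and, lower, Oas1a (-3.63 ± 0.48). Stat2, Irf9 and Irf1 had log2 fold changes of 1.07 ± 0.21, 1.24 ± 0.18 and 0.96 ± 0.30, Ifnlr1 was 3.17 times higher and Irf7 2.89 times lower (-1.53 ± 0.28, adjusted p = 2.39e-04). The call of Irf1 was lost without colon replicate 2 or lung replicate 2 (adjusted p 0.0551 to 0.0779).

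Other sets differed between lung and colon. Cell cycle genes were lower in lung for 20 of 20 (median log2 fold change -4.99, adjusted p = 1.66e-08, and adjusted p = 0.783 with an estimated correlation), such as Ube2c (-6.62 ± 0.43), and endothelial markers higher for 11 of 12 (median log2 fold change 3.31, adjusted p = 0.00720, and adjusted p = 0.941 with an estimated correlation), such as Kdr (4.21 ± 0.68). Foxn1 was lower in lung (-4.87 ± 0.50, adjusted p = 9.99e-07), while Aire and Psmb11 were near the floor in both. Sets that did not pass were MHC class II with 9 higher and 2 lower (adjusted p = 0.0706), non-classical MHC class I with 3 and 7 (adjusted p = 0.656), MHC class I regulators with 6 and 6 (adjusted p = 0.835) and autophagy genes with 11 and 2 (adjusted p = 0.0549). Cd74 was higher (4.25 ± 0.37) and Ctss lower (-3.97 ± 0.40). The same held for fibroblast markers with 10 higher and 1 lower (adjusted p = 0.0649), myeloid markers with 9 and 3 (adjusted p = 0.182), tuft markers with Ptgs1 higher and 8 lower (adjusted p = 0.0706) and skin markers with 10 and 4 (adjusted p = 0.296). The 11 other lists did not pass either (adjusted p 0.220 to 0.981). Csf1r, a macrophage receptor gene, stood at 539 ± 57.6 CPM in lung and was 536 times higher than in colon (9.07 ± 0.58, adjusted p = 6.90e-09). A total of 11204 genes differed, 5802 higher and 5402 lower in lung. Of the 26 lists 6 passed with the preset correlation, 0 with an estimated correlation and 17 with fry. Without lung replicate 3 the lists called numbered 10, and against a threshold of a 2-fold change 6474 genes passed.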

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

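The tests of leukocytes in skin, of medullary cells in cTEC replicate 3 and of myeloid cells in lung were chosen only after the result was seen. Skin replicate 1 had 10.603% of its strand-assigned gene reads on the opposite strand, a signal in a count column that no comparison uses, against 4.931% to 7.158% in the 14 other libraries. The same library had 14.801% of its gene reads in Gm42418.

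Nlrc5 was lower in thymic epithelium than in skin (log2 fold change -0.96) while 14 of the 17 MHC class I genes were higher. Taken singly, cTEC passed against skin for Nlrc5 and mTEC did not. Reads lost to other genes were argued against, because estimated counts that divide shared reads gave -0.90 (adjusted p = 0.00577). The mean RSEM length in skin was 0.937 of that in thymic epithelium, which does not bear on the pattern, since a shorter transcript would give fewer reads in skin. Leukocytes in the skin libraries were argued against by the leukocyte gene Ptprc, which reached at most 0.0152 of the Nlrc5 level in a skin library. Endothelial and fibroblast markers were also higher in skin, for 12 of 12 genes each, and a share of Nlrc5 from such cells was not tested. A difference between the tissues may account for the pattern and stays a hypothesis, since the pattern was found and tested on the same libraries.

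cTEC replicate 3 had higher cortical markers than cTEC replicates 1 and 2, with a median ratio of 2.08 over 11 genes, and fewer genes detected. Fewer medullary cells stay open. The cortical markers would need a medullary share of 55.9% in replicates 1 and 2, which is 3.30 times the median level of medullary genes relative to mTEC (17.0%), but the median ratio over medullary genes was 0.868. Fewer thymocytes cannot be told apart from no change, since the median ratio over 19 thymocyte genes was 0.860. A difference among pools of mice could also account for it and was not tested.

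Csf1r, known from macrophages, reached 539 CPM in lung. Myeloid cells were argued against, because the median of the other 16 myeloid genes was at most 0.00222 of Csf1r in a lung library, although Lyz2, which alveolar epithelium also expresses, reached 1892 CPM. Estimated counts were at least 0.960 of the read counts, so the estimate did not move many of these reads to other genes. Reads running on from a neighbouring gene on the same strand would count in both, so that explanation stays untested. Expression in the sorted lung cells may account for it and stays a hypothesis.

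Other splits of the libraries were set against each count of genes. For thymus with periphery 1 of 100 splits, the real one, gave as many calls (12268, highest other 780). For thymus with skin it was 1 of 84 (11695, highest other 5713). That other split set cTEC replicate 3 and mTEC replicates 1 and 3 against the rest, which held all skin libraries. A random draw divided the rest into 2 groups, so the count belongs to that draw. With cTEC replicate 1 and mTEC replicates 1 and 3 on that side it was 5283. With cTEC replicate 3 and mTEC replicates 2 and 3 it was 0. For mTEC with cTEC (4714, highest other 0) and lung with colon (11204, highest other 1) the 10 splits are too few for a share under 0.05. In the first of these, 3 of the 9 other splits part as many pairs of replicate numbers as the real one and gave 0 calls, and the other 6 keep some pairs together. For the MHC class I genes past the test among 5 groups it was 1 of 100 (17, highest other 3). Splits that mix tissues carry the differences between tissues into the spread within a side, so the counts for thymus with periphery, thymus with skin and the 5 groups do not show whether chance can be excluded, or whether another grouping of whole tissues would give as many. For the lists called between thymus and periphery, 7 of 100 splits gave as many as the real 16, and the highest other gave 19, so chance cannot be excluded for that count.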

How the results depend on the processing

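The runs without repeat and mitochondrial genes, without both doubted libraries (cTEC replicate 3 and skin replicate 1) and with a replicate block on thymic libraries alone were chosen after seeing the data, as was the detection without repeat genes. Of 11255 values of named genes under all alternatives 10929 kept direction and side of the threshold, 286 lost the call, 19 gained one and 21 turned direction, none of the last among the 509 values called. Except where a cause is given, the cause was not tested.

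Tested against a 2-fold change, which asks for more than a difference from 0, the counts were 1158 (921 higher, 237 lower) for mTEC with cTEC and 5684 (4231 and 1453) for thymus with periphery. They were 6108 (4129 and 1979) for thymus with skin and 6474 (3578 and 2896) for lung with colon. All other settings left the last 3 counts within 1.5 times. For mTEC with cTEC, leaving out 1 library gave 2408 (without mTEC replicate 1) to 4207 genes, with 1513 to 2721 higher and 895 to 1486 lower. Without cTEC replicate 2 it was 3075, 1819 of them higher. Without both doubted libraries it was 4370. The thymic libraries alone gave 5659 without a block and 7091 with the replicate block, 3167 of the latter lower. The replicate block in the fit of all 15 libraries gave 4431, and blocking moved no other main count past 1.5 times. DESeq2 gave 5690. With no filter the share higher was 72.2% instead of 61.7%. Adding genes of low counts also raised the median log2 fold change of all genes by 0.147, 0.336 and 0.660 for mTEC with cTEC, thymus with periphery and thymus with skin. Depth limits genes near the floor of 3 reads.

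With an estimated correlation 0 lists were called in any of the 4 comparisons, a larger variance being allowed for related genes. This held for the MHC class I list with medians of 1.84 (periphery) and 1.15 (skin), and in the pairs of mTEC with skin, colon and lung (1.01, 2.15 and 2.01) and of cTEC with them (1.21, 2.13 and 1.95). With fry 23 lists were called for thymus with skin and 17 for lung with colon, as it does not compare a list with other genes, and the MHC class I list gained a call in the latter (median 0.24, adjusted p = 0.0345). With no filter 11 lists were called for lung with colon, 5 more than with it. Leaving out 1 library gave 7 to 14 lists for mTEC with cTEC and 6 to 10 for lung with colon. Of the 60 list calls none turned direction. The MHC class I list in mTEC with cTEC had a median of 0.00289 to 0.182 on leaving out 1 library and -0.000349 without both doubted libraries. The interferon-stimulated list there had 0.12 without cTEC replicate 2 and -0.49 without mTEC replicate 2.

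With no filter 14 lists short of the threshold passed, the interferon-stimulated list in mTEC with cTEC among them. For thymus with periphery they were MHC class I regulators (adjusted p = 0.0141), interferons and receptors (adjusted p = 0.0422), colon (adjusted p = 0.0121), pan-epithelial (adjusted p = 0.0126), erythroid (adjusted p = 0.0199) and autophagy (adjusted p = 0.0215). For thymus with skin they were interferons and receptors (adjusted p = 0.0290) and tuft (adjusted p = 0.0308). For lung with colon they were MHC class II (adjusted p = 0.00987), tuft (adjusted p = 0.0197), myeloid (adjusted p = 0.0409), fibroblast (adjusted p = 0.00788) and autophagy (adjusted p = 0.00620). With fry it was 34. Other settings also gave calls to lists short of the threshold, where a number after a group is a replicate left out. In mTEC with cTEC this held for skin with the filter at 1 CPM, with the replicate block, on thinned counts, without repeat and mitochondrial genes, with the block on thymic libraries alone and without mTEC 2 (adjusted p 0.0270 to 0.0476). In thymus with periphery this held for MHC class I regulators with upper quartile scaling, with the filter at 1 CPM, on thinned counts and without mTEC 1 or 3 (adjusted p 0.0414 to 0.0498), for colon with upper quartile scaling, on thinned counts and without cTEC 3, mTEC 1, skin 3 or colon 2 (adjusted p 0.0362 to 0.0451), for pan-epithelial with upper quartile scaling, with unstranded counts and without cTEC 2 or 3, mTEC 2, skin 3, colon 2 or 3 or lung 3 (adjusted p 0.0350 to 0.0494) and for autophagy with estimated counts, without both doubted libraries and without mTEC 2, skin 1, colon 3 or lung 1 (adjusted p 0.0351 to 0.0493). In thymus with skin this held for interferons and receptors without cTEC 2, mTEC 3 or skin 1 (adjusted p 0.0399 to 0.0443), for lung without both doubted libraries and without skin 1 (adjusted p 0.0238 to 0.0419) and for tuft without both doubted libraries (adjusted p = 0.0410). In lung with colon this held for autophagy with estimated counts, with unstranded counts and without lung 1 or 3 (adjusted p 0.0300 to 0.0438), for MHC class II without colon 1 or lung 3 (adjusted p 0.0365 to 0.0378), for fibroblast without colon 3 or lung 3 (adjusted p 0.0401 to 0.0438) and for tuft without lung 3 (adjusted p = 0.0438).

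Medians of called lists moved past 1.5 times in some cases. Cell cycle in thymus with skin stood at -0.92 without skin replicate 3, and colon there at 4.83 without skin replicate 1 and 4.90 without both doubted libraries. Lung in thymus with periphery stood at -0.52 and -0.64 in the same order. For mTEC with cTEC tuft stood at 1.29 and 0.52 without cTEC replicates 1 and 3 and B cell at 1.12 on thinned counts.

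Without both doubted libraries the calls lost for mTEC with cTEC included those of Nlrc5 (adjusted p = 0.0847), Tap2 (adjusted p = 0.0823), Psmb10 (adjusted p = 0.0958), Ifngr1 (adjusted p = 0.114), Psmb4 (adjusted p = 0.103), Pou2f3 (adjusted p = 0.171) and Cd68 (adjusted p = 0.0975), and of the tuft (adjusted p = 0.193) and B cell lists (adjusted p = 0.101). The log2 fold changes moved from 0.82 to 0.79 for Nlrc5, -0.45 to -0.38 for Tap2 and -0.67 to -0.45 for Psmb10. For Ifngr1, Psmb4, Pou2f3 and Cd68 they moved from 0.73 to 0.70, -0.44 to -0.33, 0.88 to 0.66 and -0.65 to -0.53. The interferon-stimulated list in mTEC with cTEC gained a call (median log2 fold change -0.37, adjusted p = 0.00123). For thymus with skin the calls lost were those of Psma7 (adjusted p = 0.132) and Psma4 (adjusted p = 0.234). Without repeat and mitochondrial genes the calls of Nlrc5 (adjusted p = 0.0505) and Ifngr1 (adjusted p = 0.0505) in mTEC with cTEC were lost. Their log2 fold changes moved little, from 0.82 to 0.79 and from 0.73 to 0.70.

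Some genes that did not pass turned direction. Psmb8 in mTEC with cTEC stood at -0.0410 with unstranded counts, -0.0406 with the compared groups alone, -0.0265 without repeat and mitochondrial genes, -0.149 without both doubted libraries and -0.0179 with the replicate block on the thymic libraries alone. Leaving out 1 library gave -0.146 to 0.191. H2-D1 stood at -0.0151, Ifnlr1 at -0.0497 and Stat2 at -0.0229 without both doubted libraries. On leaving out 1 library they ran over -0.0116 to 0.182, -0.119 to 0.331 and -0.0795 to 0.151. Psmb9 in lung with colon stood at 0.0202 with estimated counts and 0.00404 on thinned counts, and leaving out 1 library gave -0.204 to 0.0964. The difference in genes detected was 1785 at a minimum of 5 reads, and 3024 to 5240 on leaving out 1 library.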

Other observations

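Interferon-stimulated genes varied among thymic pools. Their total was 8749, 12146 and 4696 CPM in cTEC replicates 1 to 3 and 5902, 9712 and 5119 CPM in mTEC replicates 1 to 3, and replicate 2 was highest in both. The totals of the MHC class I genes were 13676, 15997 and 12989 CPM in cTEC and 14523, 15378 and 15269 CPM in mTEC. Whether the mice of a replicate number shared an exposure is not given in the sources used here.

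Nlrc5 stood at 177 CPM in skin and 1.80 in lung, and Ifnlr1 at 29.0 CPM in skin and 84.2 in lung. Skin libraries gave 16090, 18573 and 17662 genes at the common depth. The skin mean minus the cTEC mean was -4576 (exact permutation test, p = 0.1).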
